A study of Mus musculus with 13 samples.

How the data were processed

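RNA from 13 samples of C57BL/6 mouse cells was profiled on single-colour Illumina bead arrays: embryonic stem cells of the W9.5 line (n = 2, a negative control), purified islet progenitors from pancreas at day 0 (n = 4), day 1 (n = 3) and day 4 (n = 2) of differentiation, and adult islets (n = 2, a positive control). Per the labels' protocols, total RNA was extracted with Trizol, its quality was checked on an Agilent Bioanalyser, and biotin-labelled cRNA was made with the Illumina TotalPrep kit from Ambion. The labels number the replicates of each group but do not say that they came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The series states its aim as the molecular mechanisms of differentiation of islet progenitors.

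The deposited values are log2 intensities that the authors normalized between arrays by a method that is not stated, as the near-equal quartiles of the 13 columns show. Base 2 was inferred from the range of the values, 6.73 to 15.20, whose top lies under that of a 16-bit scanner, and whether a variance-stabilising transform was used is unknown. With such a transform, differences between dim probes would be compressed. A table of signals before normalization was left out, because its column names match no sample label. Background correction of signals and a filter on detection p-values, chosen before the data were examined, were therefore replaced after the values had been seen: the deposited log2 values were used as they are, and a probe was kept if it exceeded a background level on at least 2 arrays. That level, 7.24, is the mode of the values (6.98) plus 5 times their SD below the mode (0.052). Between 44.1% and 46.4% of the probes were above it on each array.

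The array annotation gives 25697 probes, of which 23978 name 1 gene and 1719 name none, and 16593 gene symbols, of which 0 changed when updated by gene identifier. Of the probes, 14946 passed the filter (14056 with a gene name). For the 2662 genes with more than 1 passing probe the one with the highest mean over all arrays was taken, which left 10382 genes. A model with 5 group means was fitted to all 13 arrays with limma 3.58.1 (lmFit and eBayes, no intensity trend) in R 4.3.3, with 8 residual and 2.94 prior degrees of freedom, and 6 comparisons were drawn from it: day 1 against day 0, day 4 against day 0, day 4 against day 1, adult islets against day 4 and against day 0, and day 0 against embryonic stem cells. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Differences are log2 ± SE, levels are mean ± SD of log2 intensity. Where no array of a group was above background, the fold is a lower bound against the background level. Groups of 2 to 4 arrays share 1 estimate of the spread, and a comparison that leaves a group with 1 array assumes that this array varies like the others.

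Before the data were examined, 23 gene lists (509 genes, 451 on the array, 402 measured, 1 of them through a synonym) were fixed: beta cell, other islet endocrine, endocrine progenitor, secretory granule and exocytosis, genes repressed in beta cells, acinar, ductal, mesenchyme, endothelial, immune, erythroid, neural and Schwann cell, cell cycle, pluripotency, Notch and Id, sirtuin with deacetylase and NAD, Polycomb and DNA methylation, immediate early and stress, unfolded protein response, glycolysis, oxidative phosphorylation, cholesterol synthesis and interferon response. Each list with at least 5 measured members was tested with camera (inter-gene correlation 0.01, adjusted over the lists of a comparison), and again with a correlation estimated per list. Counts adjusted over the list alone use the p-values of its members only. The genes named in the text were chosen by a rule fixed in advance: the 6 largest rises and falls among called genes whose arrays do not overlap, without clone or locus names, up to 2 rises and 2 falls per list, and always Ins1, Ins2, Gcg, Sst, Ppy, Ghrl, Iapp, Pdx1, Nkx6-1, Mafa, Neurog3, Neurod1, Chga, Ucn3, Slc2a2 and Sirt1, with Pou5f1 and Nanog against embryonic stem cells. Ins1 is not analysed here, and 1 further gene of that rule is not reported here.

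The fit and the list test were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold: 75 to 85% and 95 to 99% were recovered, 4.26 to 6.84% of the calls were unchanged genes, and a shifted list was called in all 6 comparisons, with 1 other list called in day 4 against day 1. The noise of these data was drawn independently for each gene, with the same SD in every group. They therefore cannot show how unequal spread between groups, or genes that vary together, affect the calls. In the real data the estimated correlation reached 0.65, for the acinar list. The overlap of changes was compared with 100 simulated draws of unchanged groups, with noise drawn in the same way, and with the 6 splits of the day 0 arrays. Alternatives chosen in advance were no filter, a filter on whole groups, the mean of all probes, a 2-fold threshold, only the 2 groups compared, an intensity trend with robust spread, array weights, a replicate block, the progenitor arrays alone, fry in place of camera, and leaving out each array. Alternatives added after the data had been seen were quantile normalization, cyclic loess and median scaling of the deposited values, subtraction of the background level, a background level at 3 SD, and leaving out both day 0 replicate 3 and day 1 replicate 2.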

Results

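Between day 0 and day 4 of differentiation, purified mouse islet progenitors lost transcripts of Neurog3 and Pax4, transcription factors that start and direct the endocrine programme. Over the same days they gained transcripts of the secretory granule proteins Scg2 and Resp18. Neurog3 stood at 13.44 ± 0.34 (mean ± SD log2 intensity, n = 4) at day 0 and 10.14 ± 1.27 (n = 3) at day 1. It was 8.76 ± 0.29 (n = 2) at day 4 and 7.95 ± 0.45 (n = 2) in adult islets. Hormone transcripts were already close to the top of the scale at day 0, at 14.37 ± 0.35 for insulin 2 (Ins2), 14.46 ± 0.28 for glucagon (Gcg) and 13.74 ± 0.19 for somatostatin (Sst). Ins2 lay 0.13 to 0.52 log2 units under the brightest probe on the progenitor arrays and closer still on those of adult islets. Gcg lay 0.11 to 0.35 under it on the progenitor arrays, Sst 0.27 to 0.29 at day 4 and in adult islets, Ppy 0.14 to 0.16 in adult islets and ghrelin (Ghrl) 0.27 to 0.37 on 3 of the 4 day 0 arrays. Differences in the levels of these hormones, and of other transcripts near the top, can be compressed there. Embryonic stem cells lay apart from all pancreatic samples on the first principal component (49.3% of the variance). The second (23.5%) ordered the means of the pancreatic groups as day 0, day 1, day 4 and adult islets. Embryonic stem cells, at 6.55 and 2.85, lay near the day 4 progenitors on it.

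**Figure D1:**
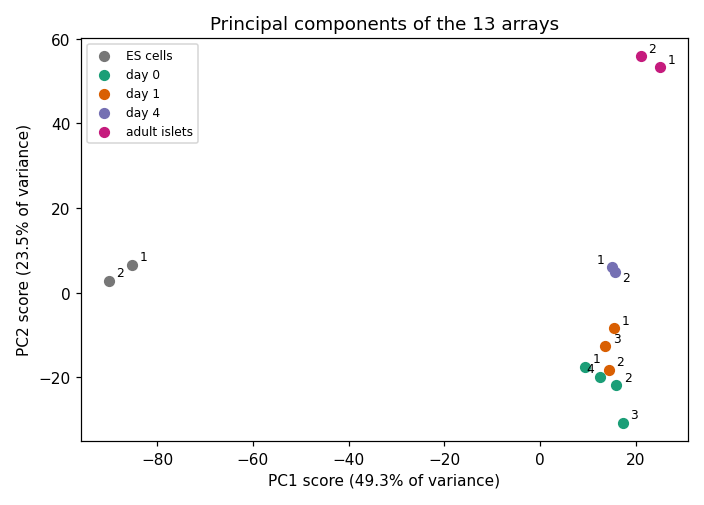
Principal components 1 and 2 of the log2 intensities of the tested genes on all 13 arrays, with the percentage of variance on each axis, colours for the 5 groups and replicate numbers beside the points. Adult islets lie at 53.3 and 55.9 on the second component and the day 4 progenitors at 5.96 and 4.88.

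In the first day of differentiation Neurog3, Pax4 and several immediate early genes fell, while Chac1 and several genes of sterol synthesis rose. Neurog3 fell by 3.30 on the log2 scale (SE 0.46, limma adjusted p = 0.00263). Pax4 changed by -2.59 ± 0.20, adjusted p = 6.35e-05, and Mfng, a glycosyltransferase that modifies Notch, by -1.58 ± 0.21, adjusted p = 0.00202. The transcription factors Fos (-3.74 ± 0.33, adjusted p = 1.49e-04), Egr1 (-2.44 ± 0.32) and Fosb (-2.40 ± 0.39) and the heat shock chaperone Hspa1a (-2.90 ± 0.43) fell as well. Large rises were those of Chac1, an enzyme that degrades glutathione (3.81 ± 0.17, adjusted p = 6.57e-07), and the amino acid transporter Slc7a3 (at least 7.89-fold over background). The mitochondrial folate enzyme Aldh1l2 (2.51 ± 0.10) and asparagine synthetase, Asns (1.94 ± 0.21), rose too. Acta1, skeletal muscle alpha actin, had the largest rise of all (4.13 ± 0.18, adjusted p = 6.57e-07). Pdyn, the dynorphin precursor (2.98 ± 0.32), and the pentraxin Nptx2 (2.70 ± 0.19) were also among the 6 largest.

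**Figure D2:**
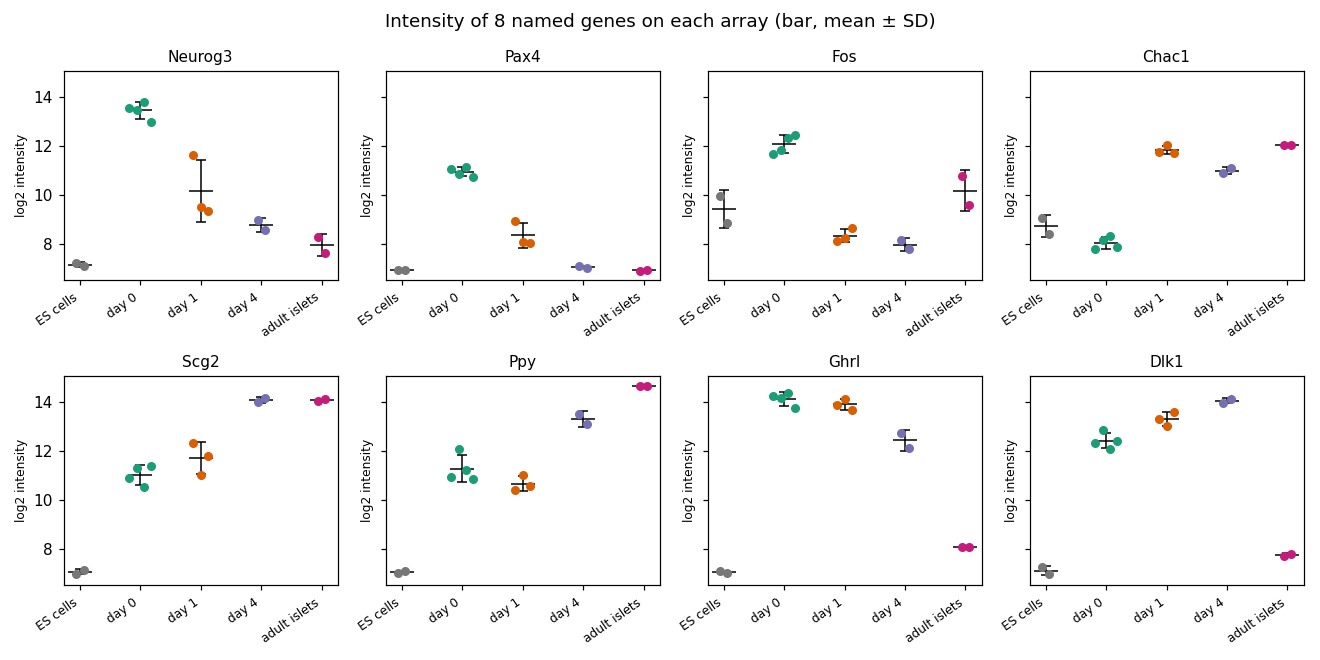
Log2 intensity of 8 genes in embryonic stem cells (n = 2), progenitors at day 0 (n = 4), day 1 (n = 3) and day 4 (n = 2) and adult islets (n = 2), with 1 point per array and bars for the mean ± SD. Chac1 rose from 8.02 at day 0 to 11.83 at day 1, while Fos fell from 12.07 to 8.32.

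Of 15 genes of cholesterol synthesis, 10 rose and 0 fell (12 and 0 adjusted over the list alone). The cholesterol synthesis median was 1.26 (adjusted p = 3.56e-15, and adjusted p = 0.15 with an estimated correlation). They include the methylsterol oxidase Msmo1 (2.47 ± 0.31) and Hmgcs1, which makes the precursor of mevalonate (2.16 ± 0.21). Immediate early and stress genes were lower as a set, with 0 of 22 higher and 9 lower past the threshold (0 and 13 adjusted over the list alone). The immediate early median was -0.71 (adjusted p = 7.91e-11, and adjusted p = 0.15 with an estimated correlation). This list was fixed as a mark of handling. Its mean level was 9.50 at day 0, 8.50 at day 1, 8.19 at day 4 and 9.40 in adult islets. Differences in handling between these groups cannot be told apart from differentiation here. Of 19 genes of the unfolded protein response, 5 rose and 0 fell (5 and 0 adjusted over the list alone), Chac1 and Asns among the risers. The unfolded protein median was 0.14 (adjusted p = 0.00337, and adjusted p = 0.15 with an estimated correlation). Without day 1 replicate 1 the call was lost (adjusted p = 0.0535, range over the alternatives 1.11e-04 to 0.15). Endocrine progenitor genes were lower as a set, with 0 of 17 higher and 2 lower past the threshold (0 and 3 adjusted over the list alone), the fallers being Neurog3 and Pax4. The endocrine progenitor median was -0.15 (adjusted p = 0.00114, and adjusted p = 0.204 with an estimated correlation). Without day 1 replicate 2 the call was lost (adjusted p = 0.0756, range over the alternatives 1.28e-05 to 0.204). Of 29 cell cycle genes, 0 rose and 1 fell (0 and 3 adjusted over the list alone). The cell cycle median was -0.43 (adjusted p = 1.49e-06, and adjusted p = 0.308 with an estimated correlation). Genes of oxidative phosphorylation were lower as a set, with 0 of 18 higher and 1 lower past the threshold (0 and 1 adjusted over the list alone). The oxidative phosphorylation median was -0.24 (adjusted p = 0.00662, and adjusted p = 0.15 with an estimated correlation). Without day 1 replicate 3 the call was lost (adjusted p = 0.0709, range over the alternatives 0.00185 to 0.15).

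Markers of other cell types moved beside these groups. Of 18 immune genes, 0 rose and 4 fell (0 and 7 adjusted over the list alone). The immune median was -0.42 (adjusted p = 1.32e-06, and adjusted p = 0.244 with an estimated correlation). Endothelial genes were lower as a set, with 0 of 14 higher and 1 lower past the threshold (0 and 2 adjusted over the list alone). The endothelial median was -0.24 (adjusted p = 0.00279, and adjusted p = 0.337 with an estimated correlation). Of 7 erythroid genes, 0 rose and 1 fell (0 and 2 adjusted over the list alone). The erythroid median was -0.55 (adjusted p = 0.00974, and adjusted p = 0.214 with an estimated correlation). Without day 1 replicate 1 the call was lost (adjusted p = 0.145, range over the alternatives 0.00258 to 0.214). Acinar genes were higher as a set, with 0 of 26 higher and 0 lower past the threshold (0 and 0 adjusted over the list alone). The acinar median was 0.33 (adjusted p = 0.00633, and adjusted p = 0.712 with an estimated correlation). The acinar adjusted p was 0.275 without day 0 replicate 3 and 0.628 without day 1 replicate 2, and the median was -0.24 without both (range over the alternatives 6.41e-07 to 0.712).

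Among the hormones Sst rose (0.66 ± 0.11, adjusted p = 0.0104, and 0.104 after subtraction of the background level, range over the alternatives 0.00182 to 0.109). Ins2 (0.29 ± 0.19), Gcg (0.30 ± 0.15), Ppy (-0.61 ± 0.26), Ghrl (-0.23 ± 0.18) and Iapp (-0.18 ± 0.31) did not pass. Beta cell genes did not pass as a set (median -0.09, adjusted p = 0.27), with 0 of 19 genes higher and 2 lower (0 and 2 adjusted over the list alone). Their member Slc30a8, the granule zinc transporter, fell (-1.13 ± 0.20, adjusted p = 0.0116, and 0.0572 without day 1 replicate 3, range over the alternatives 0.00232 to 0.0885). Pdx1 (0.05 ± 0.20), Nkx6-1 (0.11 ± 0.23), Neurod1 (-0.48 ± 0.37), Mafa (0.11 ± 0.13) and Sirt1 (0.15 ± 0.21) did not pass, nor did Ucn3, which no day 1 array showed above background. Nor did Slc2a2 (-0.48 ± 0.29) and Chga (-0.65 ± 0.24), where 2 of 3 and 1 of 3 probes had the opposite sign. In all, 454 of 10382 genes passed, 208 higher and 246 lower, and 131 differed at least 2-fold. The count was 243 without day 1 replicate 2, 202 without day 1 replicate 3 and 260 without both day 0 replicate 3 and day 1 replicate 2. Of the 33 named genes called, 10 lost the call without day 1 replicate 2 and 12 without day 1 replicate 3.

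By day 4 the progenitors had lost most of their Neurog3 and Pax4 signal. They carried more transcripts of the granule proteins Scg2 and Resp18 and of pancreatic polypeptide, and fewer of ghrelin and gastrin. Neurog3 fell by 4.68 on the log2 scale (SE 0.52, adjusted p = 4.43e-04), and Pax4 was at least 13-fold lower, since no day 4 array was above background. Scg2, a granin of dense core granules, rose by 3.08 ± 0.31, adjusted p = 2.65e-04, and Resp18, a neuroendocrine granule protein, by 2.30 ± 0.23, adjusted p = 2.65e-04. Bace2, an aspartyl protease of beta cells, rose by 3.02 ± 0.17, adjusted p = 6.89e-06. Pancreatic polypeptide, Ppy (2.04 ± 0.30, adjusted p = 0.00217), and Sst (0.84 ± 0.13, adjusted p = 0.00287) rose. Ghrelin, Ghrl (-1.70 ± 0.20, adjusted p = 6.29e-04), and gastrin, Gast (-2.92 ± 0.35, adjusted p = 6.95e-04), fell. Pdyn (4.10 ± 0.36) and Acta1 (3.37 ± 0.21) were again among the largest rises.

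Of 22 genes of secretory granules and exocytosis, 8 rose and 1 fell (10 and 1 adjusted over the list alone), the granin Chgb being the 1 that fell. The granule gene median was 0.40 (adjusted p = 9.58e-06, and adjusted p = 0.156 with an estimated correlation). Endocrine progenitor genes were lower as a set, with 0 of 17 higher and 4 lower past the threshold (0 and 5 adjusted over the list alone). The endocrine progenitor median was -0.34 (adjusted p = 6.12e-04, and adjusted p = 0.156 with an estimated correlation). Of 22 immediate early and stress genes, 0 rose and 10 fell (0 and 15 adjusted over the list alone). The immediate early median was -0.89 (adjusted p = 8.38e-09, and adjusted p = 0.156 with an estimated correlation). Fos changed by -4.11 ± 0.37 and Hspa1a by -4.60 ± 0.49. Cholesterol synthesis genes were higher as a set, with 6 of 15 higher and 0 lower past the threshold (10 and 0 adjusted over the list alone). The cholesterol synthesis median was 0.97 (adjusted p = 7.03e-08, and adjusted p = 0.156 with an estimated correlation). Of 19 genes of the unfolded protein response, 5 rose and 1 fell (7 and 1 adjusted over the list alone). The unfolded protein median was 0.48 (adjusted p = 0.00455, and adjusted p = 0.156 with an estimated correlation). Risers among them were Chac1 (2.97 ± 0.19) and Asns (1.70 ± 0.23). Cell cycle genes were higher as a set, with 2 of 29 higher and 0 lower past the threshold (2 and 0 adjusted over the list alone). The cell cycle median was 0.41 (adjusted p = 1.44e-04, and adjusted p = 0.493 with an estimated correlation). Of 18 genes of oxidative phosphorylation, 0 rose and 1 fell (0 and 1 adjusted over the list alone). The oxidative phosphorylation median was -0.38 (adjusted p = 0.0288, and adjusted p = 0.156 with an estimated correlation). Without day 0 replicate 1 the call was lost (adjusted p = 0.0574, range over the alternatives 0.00353 to 0.156).

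Red cell transcripts were near background at day 4. Hba-a1, an alpha globin, fell by 6.87 on the log2 scale (SE 0.86, adjusted p = 8.74e-04). Erythroid genes were lower as a set, with 0 of 7 higher and 3 lower past the threshold (0 and 4 adjusted over the list alone). The erythroid median was -1.10 (adjusted p = 0.0053, and adjusted p = 0.156 with an estimated correlation). Of 18 immune genes, 1 rose and 5 fell (1 and 6 adjusted over the list alone). The immune median was -0.46 (adjusted p = 0.00403, and adjusted p = 0.529 with an estimated correlation). For acinar genes the median and the mean differ in sign, -0.21 and 0.21 (test direction up, adjusted p = 0.612). Of these 26 genes, 4 rose and 2 fell (5 and 3 adjusted over the list alone). Other islet endocrine genes also had a median and a mean of opposite sign, 0.05 and -0.22 (test direction down, adjusted p = 0.889). Of these 12 genes, 2 rose and 4 fell (3 and 4 adjusted over the list alone). Beta cell genes did not pass as a set (median 0.16, adjusted p = 0.271), with 3 of 19 genes higher and 0 lower (3 and 0 adjusted over the list alone). Ins2 (0.32 ± 0.22), Gcg (0.22 ± 0.17), Iapp (0.67 ± 0.35), Slc2a2 (0.93 ± 0.32) and Chga (0.45 ± 0.27) did not pass. Pdx1 (-0.34 ± 0.22), Nkx6-1 (-0.40 ± 0.27), Neurod1 (-0.94 ± 0.42), Ucn3 (0.16 ± 0.12), Mafa (0.40 ± 0.15) and Sirt1 (-0.22 ± 0.23) did not pass either.

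In this comparison 1188 genes passed, 560 higher and 628 lower (47.1% higher, and 52.9% after median scaling), and 349 of them differed at least 2-fold. The count was 193 without day 4 replicate 1 and 217 without day 4 replicate 2, and 31 and 32 of the 53 named genes called then lost the call, Chgb among them. Neurog3, Pax4, Scg2, Resp18, Bace2, Ppy, Sst, Ghrl and Gast passed without either array.

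**Figure D3:**
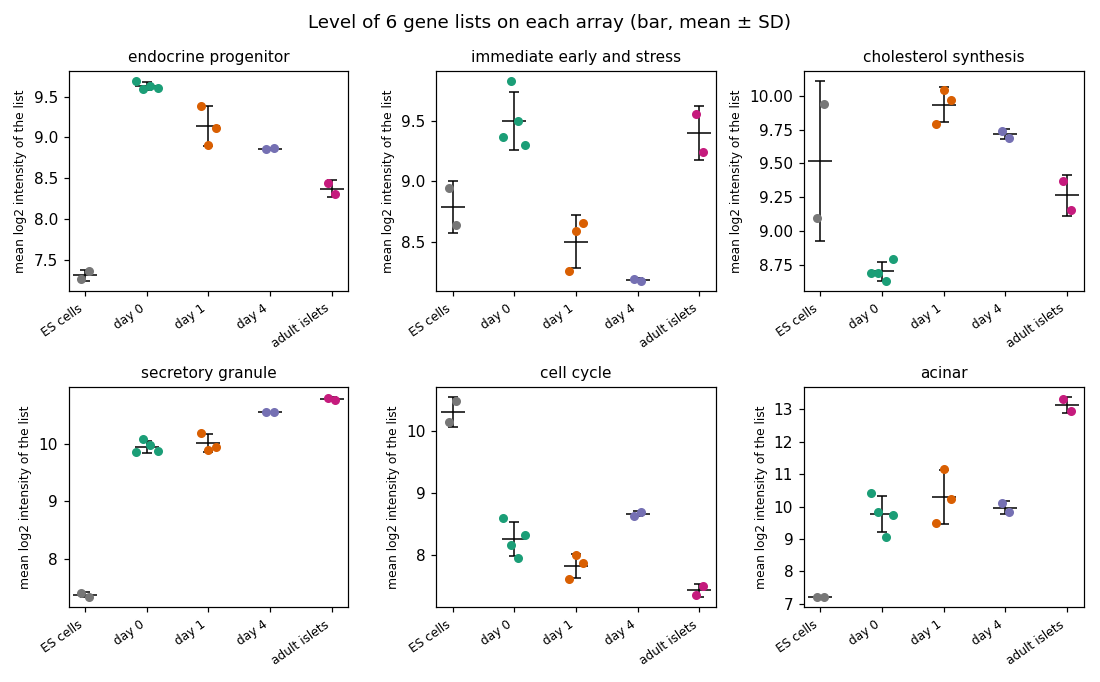
Mean log2 intensity of the measured genes of 6 lists in the 5 groups (embryonic stem cells n = 2, day 0 n = 4, day 1 n = 3, day 4 n = 2, adult islets n = 2), with 1 point per array and bars for the mean ± SD over arrays. The cell cycle list stood at 7.82 at day 1 and 8.66 at day 4, and the acinar list at 9.96 at day 4 and 13.13 in adult islets.

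Between day 1 and day 4 the progenitors gained transcripts of some genes of cell division and of hormone granules. Cell cycle genes were higher as a set, with 3 of 29 higher and 0 lower past the threshold (18 and 0 adjusted over the list alone). The cell cycle median was 0.75 (adjusted p = 8.85e-18, and adjusted p = 0.19 with an estimated correlation). Topoisomerase Top2a was among the risers (1.73 ± 0.26, adjusted p = 0.0111), and Pbk, a mitotic kinase, rose by 2.56 ± 0.37. Of 22 granule and exocytosis genes, 3 rose and 0 fell (6 and 0 adjusted over the list alone). The granule gene median was 0.38 (adjusted p = 3.34e-07, and adjusted p = 0.0834 with an estimated correlation). Resp18 (2.42 ± 0.25, adjusted p = 0.00169) and Scg2 (2.39 ± 0.33, adjusted p = 0.0106) were among those that rose. Ppy (2.65 ± 0.31, adjusted p = 0.00521), the neuropeptide Npy (2.57 ± 0.35), the islet glucose-6-phosphatase G6pc2 (2.75 ± 0.46) and Slc30a8 (1.77 ± 0.24) rose. Ghrl (-1.47 ± 0.21, adjusted p = 0.0106), Hba-a1 (-6.32 ± 0.90) and Mdk, the growth factor midkine (-1.95 ± 0.20, adjusted p = 0.00164, 1 of 4 probes with the opposite sign), fell. The comparison called 161 genes, 103 higher and 58 lower, 73 of them at least 2-fold. This count was 359 without day 1 replicate 1, 107 without day 1 replicate 2, 37 without day 1 replicate 3, 8 without day 4 replicate 1 and 12 without day 4 replicate 2. Without day 4 replicate 1 or 2 only 3 or 4 of the 22 named genes called passed, Resp18 and Mdk in both cases.

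Beta cell genes were higher as a set, with 2 of 19 higher and 0 lower past the threshold (5 and 1 adjusted over the list alone), the risers being G6pc2 and Slc30a8. The beta cell median was 0.11 (adjusted p = 0.033, and adjusted p = 0.723 with an estimated correlation). This call was lost in several alternatives, among them leaving out day 4 replicate 2 and fry (adjusted p = 0.185). With camera it was also lost after cyclic loess (0.0562) and after median scaling (0.0528, range over the alternatives 0.0133 to 0.723). Acinar genes did not pass as a set (median -0.32, adjusted p = 0.202), with 1 of 26 genes higher and 0 lower (1 and 1 adjusted over the list alone). Neurog3 (-1.38 ± 0.55), Chga (1.10 ± 0.28), Slc2a2 (1.41 ± 0.34), Iapp (0.85 ± 0.37), Ins2 (0.03 ± 0.23) and Gcg (-0.08 ± 0.17) did not pass.

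Adult islets had high levels of digestive enzyme, immune, endothelial and stress transcripts and of the beta cell peptide urocortin 3 beside day 4 progenitors. Cell cycle genes, ghrelin, secretin and the imprinted gene Dlk1 were low in them. Of the other hormones, pancreatic polypeptide was higher, and Ins2, Gcg, Sst and Iapp did not pass. Ucn3, a peptide of mature beta cells, rose by 4.64 ± 0.14, adjusted p = 1.20e-08, from 7.42 ± 0.06 to 12.06 ± 0.27. Ghrl fell by 4.37 on the log2 scale (SE 0.23, adjusted p = 7.14e-07), and secretin, Sct, changed by -4.84 ± 0.41. The imprinted growth regulator Dlk1 (-6.30 ± 0.24, adjusted p = 4.24e-08), the tight junction protein Cldn11 (-5.43 ± 0.20), the imprinted gene Nnat (-4.31 ± 0.73) and the amino acid transporter Slc38a5 (-3.97 ± 0.30) fell. The 6 largest rises were all exocrine genes. They were the protease Ctrl (7.20 ± 0.18, adjusted p = 2.83e-09), the elastases Cela1 (6.44 ± 0.71) and Cela3b (5.48 ± 0.56), the zymogen granule protein Zg16 (6.00 ± 0.64), the lipase Cel (5.72 ± 0.72) and the trypsin Prss2 (5.49 ± 0.55).

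Of 26 acinar genes, 14 rose and 0 fell (17 and 0 adjusted over the list alone). The acinar median was 2.62 (adjusted p = 8.29e-17, and adjusted p = 0.12 with an estimated correlation). Immune genes were higher as a set, with 15 of 18 higher and 0 lower past the threshold (16 and 0 adjusted over the list alone). The immune median was 1.56 (adjusted p = 2.22e-14, and adjusted p = 0.0796 with an estimated correlation). Cd74, the class II invariant chain, was at least 23.4-fold over background. Of 17 interferon response genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone). The interferon median was 1.48 (adjusted p = 2.52e-14, and adjusted p = 0.0796 with an estimated correlation). Ifit3, which interferon induces, rose by 4.43 ± 0.44. Endothelial genes were higher as a set, with 11 of 14 higher and 0 lower past the threshold (11 and 0 adjusted over the list alone). The endothelial median was 1.42 (adjusted p = 2.47e-10, and adjusted p = 0.0796 with an estimated correlation). Plvap, a protein of endothelial diaphragms, was at least 14.8-fold over background. Mesenchyme genes did not pass as a set (median -0.25, adjusted p = 0.835), with 0 of 22 genes higher and 0 lower (0 and 0 adjusted over the list alone). Ductal genes did not pass as a set (median -0.13, adjusted p = 0.941, mean -0.03, test direction up), with 3 of 14 genes higher and 2 lower (3 and 3 adjusted over the list alone).

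Of 22 immediate early and stress genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone). The immediate early median was 0.96 (adjusted p = 6.92e-09, and adjusted p = 0.0975 with an estimated correlation). Socs3, an inhibitor of cytokine signals, rose by 3.47 ± 0.23. Genes of the unfolded protein response were higher as a set, with 7 of 19 higher and 0 lower past the threshold (13 and 0 adjusted over the list alone). The unfolded protein median was 0.85 (adjusted p = 1.13e-07, and adjusted p = 0.0415 with an estimated correlation). Ddit3, a stress transcription factor, rose by 3.13 ± 0.31. Of 29 cell cycle genes, 0 rose and 21 fell (0 and 22 adjusted over the list alone). The cell cycle median was -1.33 (adjusted p = 3.39e-13, and adjusted p = 0.101 with an estimated correlation). The replication factor Mcm5 fell (-2.80 ± 0.39). Other islet endocrine genes were lower as a set, with 1 of 12 higher and 5 lower past the threshold (1 and 6 adjusted over the list alone), the riser being Ppy. The islet endocrine median was -0.33 (adjusted p = 0.0112, and adjusted p = 0.0796 with an estimated correlation). Of 17 endocrine progenitor genes, 0 rose and 3 fell (0 and 4 adjusted over the list alone). The endocrine progenitor median was -0.23 (adjusted p = 0.0202, and adjusted p = 0.265 with an estimated correlation). The transcription factor Myt1 fell (-1.50 ± 0.17). Genes of oxidative phosphorylation were lower as a set, with 0 of 18 higher and 1 lower past the threshold (0 and 1 adjusted over the list alone). The oxidative phosphorylation median was -0.30 (adjusted p = 0.0114, and adjusted p = 0.0999 with an estimated correlation). After cyclic loess the call was lost (adjusted p = 0.0829, range over the alternatives 0.00161 to 0.0999).

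The beta cell list had a median of -0.10 and a mean of 0.25 (test direction up, adjusted p = 0.675), with 3 of 19 genes higher and 3 lower (4 and 4 adjusted over the list alone). Ucn3 and the ion channel Trpm5 (2.79 ± 0.19) rose, and the transcription factor Isl1 (-1.43 ± 0.24) fell. Granule genes did not pass as a set (median 0.01, adjusted p = 0.4), with 3 of 22 genes higher and 2 lower (6 and 3 adjusted over the list alone). Syt4, a synaptotagmin, rose by 2.93 ± 0.16. Ppy (1.36 ± 0.34, adjusted p = 0.0217) and Chga, chromogranin A (1.11 ± 0.31, adjusted p = 0.0342), passed. Without adult islet replicate 1, adult islet replicate 2, day 4 replicate 1 or day 4 replicate 2 the adjusted p of Ppy was 0.104, 0.107, 0.0565 or 0.174, and that of Chga 0.159, 0.129, 0.154 or 0.153. The range over the alternatives was 3.28e-04 to 0.174 for Ppy and 2.20e-04 to 0.159 for Chga. Ins2 (0.08 ± 0.25), Gcg (-0.10 ± 0.19), Sst (-0.03 ± 0.15), Iapp (-0.01 ± 0.40), Pdx1 (-0.75 ± 0.26) and Nkx6-1 (-0.75 ± 0.31) did not pass. Neurod1 (-0.46 ± 0.49), Neurog3 (-0.81 ± 0.60), Slc2a2 (0.73 ± 0.37), Mafa (-0.23 ± 0.18) and Sirt1 (0.16 ± 0.27) did not pass either.

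In total 1501 genes differed between adult islets and day 4, 782 higher and 719 lower in islets (52.1% higher, and 63.7% after cyclic loess), and 695 of them at least 2-fold. The count was 695 without day 4 replicate 1, 675 without day 4 replicate 2, 859 without adult islet replicate 1 and 781 without adult islet replicate 2. Of the 57 named genes called, 15 to 20 then lost the call.

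Against day 0, adult islets had far less ghrelin, Neurog3 and midkine and far more exocrine enzyme and urocortin 3 transcripts. Ghrl fell by 6.06 on the log2 scale (SE 0.20, adjusted p = 8.55e-09) and Neurog3 by 5.49 (SE 0.52, adjusted p = 2.07e-05). Mdk changed by -5.24 ± 0.19, and Gast was at least 28-fold lower. Ctrl (7.33 ± 0.15, adjusted p = 4.88e-10) and the kallikreins Klk1 (5.38 ± 0.29) and Klk1b27 (5.55 ± 0.16) rose. Gp2, a zymogen granule membrane protein, was at least 56.6-fold higher. Ucn3 (4.80 ± 0.12, adjusted p = 1.47e-09), Ppy (3.40 ± 0.30), Syt4 (4.35 ± 0.14) and G6pc2 (3.10 ± 0.43) rose. So did the glucose transporter Slc2a2 (1.66 ± 0.32, adjusted p = 0.00256), Chga (1.56 ± 0.27) and Sst (0.82 ± 0.13). Ins2 (0.40 ± 0.22), Gcg (0.12 ± 0.17), Iapp (0.66 ± 0.35), Mafa (0.16 ± 0.15) and Sirt1 (-0.06 ± 0.23) did not pass.

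Of 17 endocrine progenitor genes, 0 rose and 11 fell (0 and 11 adjusted over the list alone). The endocrine progenitor median was -0.98 (adjusted p = 9.42e-05, and adjusted p = 0.142 with an estimated correlation). The endocrine transcription factors Isl1 (-1.65 ± 0.20), Nkx2-2 (-1.85 ± 0.26), Pdx1 (-1.10 ± 0.22, adjusted p = 0.00344), Nkx6-1 (-1.15 ± 0.27, adjusted p = 0.00675) and Neurod1 (-1.40 ± 0.42, adjusted p = 0.0253) were lower in islets than at day 0. Whether a lower endocrine share of the islet RNA contributes to these falls was not tested. Without adult islet replicate 2 the adjusted p was 0.0524 for Pdx1, 0.0871 for Nkx6-1 and 0.116 for Neurod1. Without adult islet replicate 1 it was 0.13 for Neurod1. The range over the alternatives was 9.51e-04 to 0.0524 for Pdx1, 0.00184 to 0.0871 for Nkx6-1 and 0.00137 to 0.13 for Neurod1. Beta cell genes did not pass as a set (median 0.15, adjusted p = 0.244), with 6 of 19 genes higher and 6 lower (6 and 7 adjusted over the list alone). Granule genes were higher as a set, with 10 of 22 higher and 2 lower past the threshold (10 and 2 adjusted over the list alone). The granule gene median was 0.35 (adjusted p = 9.09e-04, and adjusted p = 0.142 with an estimated correlation). Of 19 genes of the unfolded protein response, 12 rose and 0 fell (14 and 0 adjusted over the list alone). The unfolded protein median was 1.39 (adjusted p = 3.82e-08, and adjusted p = 0.0291 with an estimated correlation). Chac1 rose by 4.01 ± 0.19 and Ddit3 by 3.44 ± 0.27. Cholesterol synthesis genes were higher as a set, with 4 of 15 higher and 0 lower past the threshold (4 and 0 adjusted over the list alone). The cholesterol synthesis median was 0.36 (adjusted p = 0.0255, and adjusted p = 0.515 with an estimated correlation). Without adult islet replicate 1 the call was lost (adjusted p = 0.105, range over the alternatives 0.00734 to 0.515). Of 29 cell cycle genes, 0 rose and 18 fell (0 and 18 adjusted over the list alone). The cell cycle median was -1.03 (adjusted p = 3.10e-05, and adjusted p = 0.357 with an estimated correlation). Mcm5 changed by -2.05 ± 0.34. Genes of oxidative phosphorylation were lower as a set, with 0 of 18 higher and 13 lower past the threshold (0 and 13 adjusted over the list alone). The oxidative phosphorylation median was -0.74 (adjusted p = 4.05e-04, and adjusted p = 0.0909 with an estimated correlation). Atp5b, a subunit of ATP synthase, changed by -1.53 ± 0.21.

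Acinar, immune, endothelial and interferon response genes were also higher in islets. Of 26 acinar genes, 19 rose and 2 fell (22 and 2 adjusted over the list alone). The acinar median was 4.30 (adjusted p = 1.10e-11, and adjusted p = 0.255 with an estimated correlation). Immune genes were higher as a set, with 9 of 18 higher and 0 lower past the threshold (9 and 0 adjusted over the list alone). The immune median was 0.87 (adjusted p = 1.49e-06, and adjusted p = 0.255 with an estimated correlation). Of 17 interferon response genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone). The interferon median was 1.39 (adjusted p = 4.31e-11, and adjusted p = 0.142 with an estimated correlation). Endothelial genes were higher as a set, with 11 of 14 higher and 0 lower past the threshold (12 and 0 adjusted over the list alone). The endothelial median was 1.23 (adjusted p = 3.73e-06, and adjusted p = 0.18 with an estimated correlation). Erythroid genes did not pass as a set (median -0.96, adjusted p = 0.102), with 0 of 7 genes higher and 4 lower (0 and 4 adjusted over the list alone). Ductal genes did not pass as a set (median -0.02, adjusted p = 0.943), with 4 of 14 genes higher and 5 lower (4 and 6 adjusted over the list alone). Mesenchyme genes did not pass as a set (median -0.15, adjusted p = 0.943), with 2 of 22 genes higher and 1 lower (0 and 0 adjusted over the list alone). Of 3541 genes called, 1531 were higher and 2010 lower (43.2% higher, and 53.3% after cyclic loess or 53.7% after median scaling), and 1249 differed at least 2-fold. Without adult islet replicate 1 the count was 2048 and without adult islet replicate 2 it was 1922, with 13 and 20 of 76 named genes losing the call.

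Genes that changed from day 0 to day 4 and from day 0 to adult islets changed mostly in the same direction. In both comparisons 341 were higher and 516 lower, against 82.6 and 122 expected for unrelated lists, and 42 changed in opposite directions. The correlation of the log2 differences across genes was 0.569, where simulated unchanged groups against the same day 0 arrays gave 0.332. The covariance was 0.214 against 0.0155. With the 4 day 0 arrays split so that each comparison used its own pair, 416 to 657 genes changed alike in the 6 splits, and the covariance was 0.184 to 0.200. The 857 genes with the same direction were 173 without day 4 replicate 1, 181 without day 4 replicate 2 and 564 without adult islet replicate 2.

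Day 0 progenitors differed from embryonic stem cells by the hormones and transcription factors of the endocrine pancreas, against a stem cell signal at background. Gcg was at least 149-fold higher, Ins2 at least 140-fold, the gut peptide Pyy at least 128-fold, Ghrl at least 119-fold and Sst at least 90.4-fold. Neurog3 was at least 73.8-fold higher, Nkx6-1 at least 36.6-fold, Iapp at least 18.6-fold and Ppy at least 16.4-fold. For Pdx1 the bound was at least 13.2-fold, for Slc2a2 at least 5.5-fold and for Neurod1 at least 5.2-fold. The pluripotency factors Pou5f1 (-4.55 ± 0.17, adjusted p = 5.57e-09) and Nanog (at least 20.5-fold lower) fell. Chga rose by 5.22 ± 0.27, while Ucn3 and Mafa, which no embryonic stem cell array showed above background, did not pass. Sirt1, a protein deacetylase, was lower at day 0 (-0.97 ± 0.23, adjusted p = 0.00519, and 0.0652 without embryonic stem cell replicate 1, range over the alternatives 0.00148 to 0.0652).

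Of 18 pluripotency genes, 0 rose and 18 fell (0 and 18 adjusted over the list alone). The pluripotency median was -3.63 (adjusted p = 4.49e-17, and adjusted p = 2.88e-04 with an estimated correlation). Cell cycle genes were lower as a set, with 0 of 29 higher and 27 lower past the threshold (0 and 27 adjusted over the list alone). The cell cycle median was -2.32 (adjusted p = 8.46e-13, and adjusted p = 0.115 with an estimated correlation). Top2a changed by -3.23 ± 0.24. Of 22 granule and exocytosis genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone). The granule gene median was 2.00 (adjusted p = 1.68e-09, and adjusted p = 0.0126 with an estimated correlation). Chgb was at least 80.3-fold higher. Other islet endocrine genes were higher as a set, with 10 of 12 higher and 0 lower past the threshold (10 and 0 adjusted over the list alone). The islet endocrine median was 4.65 (adjusted p = 4.88e-08, and adjusted p = 0.00343 with an estimated correlation). Of 19 beta cell genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone). The beta cell median was 2.80 (adjusted p = 1.27e-07, and adjusted p = 0.035 with an estimated correlation). Endocrine progenitor genes were higher as a set, with 13 of 17 higher and 0 lower past the threshold (14 and 0 adjusted over the list alone). The endocrine progenitor median was 1.79 (adjusted p = 7.63e-07, and adjusted p = 0.0442 with an estimated correlation).

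Of 26 acinar genes, 21 rose and 0 fell (21 and 0 adjusted over the list alone). The acinar median was 2.35 (adjusted p = 2.24e-05, and adjusted p = 0.427 with an estimated correlation). Ductal genes were higher as a set, with 10 of 14 higher and 1 lower past the threshold (10 and 1 adjusted over the list alone). The ductal median was 1.59 (adjusted p = 0.00227, and adjusted p = 0.115 with an estimated correlation). The keratin Krt7 rose by 4.30 ± 0.28. Of 8 neural and Schwann cell genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone). The neural median was 1.06 (adjusted p = 0.0355, and adjusted p = 0.115 with an estimated correlation). Without embryonic stem cell replicate 1 the call was lost (adjusted p = 0.064, range over the alternatives 4.77e-07 to 0.115). Glycolysis genes were lower as a set, with 1 of 17 higher and 10 lower past the threshold (1 and 11 adjusted over the list alone). The glycolysis median was -0.64 (adjusted p = 0.00142, and adjusted p = 0.38 with an estimated correlation). Hexokinase 2, Hk2, changed by -3.83 ± 0.30 and the glucose transporter Slc2a1 by -3.22 ± 0.17. Of 15 Polycomb and DNA methylation genes, 3 rose and 8 fell (3 and 8 adjusted over the list alone). The Polycomb median was -1.35 (adjusted p = 0.0206, and adjusted p = 0.0952 with an estimated correlation). The DNA methyltransferase Dnmt3b changed by -3.02 ± 0.21. Cholesterol synthesis genes were lower as a set, with 0 of 15 higher and 9 lower past the threshold (0 and 9 adjusted over the list alone). The cholesterol synthesis median was -0.99 (adjusted p = 0.00595, and adjusted p = 0.423 with an estimated correlation). Without embryonic stem cell replicate 2 the call was lost (adjusted p = 0.153, range over the alternatives 1.33e-04 to 0.423). The comparison called 5120 genes, 2754 higher and 2366 lower (53.8% higher, and 47.8% after cyclic loess), 2382 of them at least 2-fold.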

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

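The tests of the acinar and red cell patterns and of the arrays that stand apart were chosen only after those results were seen, and the test of other splits of the arrays was chosen before.

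Adult islets carried far more acinar enzyme transcripts than day 4 progenitors. Of 26 measured acinar genes, 25 were higher on both islet arrays than on both day 4 arrays, among them Cela3b (14.65 ± 0.27 against 9.17 ± 0.42) and Ctrl (14.56 ± 0.10 against 7.36 ± 0.10). Of all 10382 genes, 70.9% did not overlap between these arrays, in either direction. The count restates the rise of the same list on the same arrays. Exocrine cells or their RNA carried along with the islets are a candidate source, which this count cannot tell apart from others. A lower endocrine share of the islet RNA that raises all other cell types alike is argued against as the whole cause. Immune and endothelial genes rose too (medians 1.56 and 1.42, each camera adjusted p = 0.0796 with an estimated correlation). But the upper quartile of the mesenchyme differences was 0.22 and that of the ductal ones 0.60, under the lower quartile of the acinar ones, 1.46. These values do not speak against a lower endocrine share with unequal rises. Acinar cells carried along would themselves lower that share. The labels name no sort or gate for the islets that would remove acinar cells, while the progenitors are described as purified, though 24 of the 26 genes were above background on both day 4 arrays as well (0 stand in another fixed list). A difference of age or tissue between the groups stays open, as untested.

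Haemoglobin transcripts were high at days 0 and 1 and near background at day 4, with Hba-a1 at 14.19 ± 0.61, 13.64 ± 2.10 and 7.31 ± 0.20. A single probe that binds another transcript is argued against by the fall of 1 other haemoglobin gene, Hbb-bt, from 11.18 ± 0.87 to 7.09 ± 0.14. As a set, 9 measured red cell genes had a median of -1.10 at day 4 against day 0, with 0 higher and 4 lower. Their camera adjusted p was 8.65e-04 over 24 tests, and 0.127 with an estimated correlation. Red blood cells or their RNA in the earlier samples may be the source. But only 3 of the 7 other red cell genes above background at day 0 (Hbb-bt, Alas2 and Slc4a1) were called lower at day 4. Hbb-b2, Hba-x, Hbb-y and Klf1 were not, so this source stays open. Of these 7, 1 was above background on both day 4 arrays, and the labels call the progenitors purified, by a step not described that could remove red cells. A fall of these transcripts inside the progenitors during differentiation was not tested.

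Day 0 replicate 3 and day 1 replicate 2 deviated from their groups together, with a correlation of 0.55 across genes, the highest of 12 pairs (the others -0.40 to 0.37). A different content of acinar cells is argued against, since the acinar list deviated by -0.95 on the first (SD of the other arrays 0.36) and by 1.28 on the second (SD 0.52). RNA quality or labelling stays open, since 55 ribosomal protein genes had a median deviation of -0.16 on both arrays. Over all probes, day 0 replicate 3 correlated at 0.972 with day 1 replicate 2, above its 0.960 to 0.969 with the other day 0 arrays. Day 1 replicate 2 correlated at 0.973 with day 1 replicate 3 and at 0.950 with day 1 replicate 1. An unlabelled batch shared by the pair could not be tested, since no batch is given, and stays open. No biological explanation was tested.

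Chance is argued against, but not excluded, for the count of genes called between day 1 and day 0. The real split called 454 genes, and the highest other split of the 7 arrays into 4 and 3 gave 253. That split and the next, with 200, both put day 0 replicate 3 and day 1 replicate 2, the arrays that deviated together, in the group of 3. The real split was the only 1 of 35 to give as many, which is the lowest share that this test can give. Splits that mix the days also carry any real difference in their spread, which lowers their counts.

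Of 191 day 0 values tested, 5 had 1 array far from the other 3 (gap over range), where chance gives about 5% of values. No more values stood apart than chance gives. The pluripotency list had a ratio of 0.916 (7.30 in replicate 3 against 7.22 to 7.23), close to the background level of 7.24. Klf2 had a ratio of 0.897 (10.05 in replicate 2 against 8.53 at the lowest of the others). Rsad2 had 0.882 (8.44 in replicate 1 against 9.08 to 9.16), Ndufs3 0.872 (11.13 in replicate 3 against 11.49 to 11.54) and Nfib 0.83 (8.36 in replicate 3 against 9.11 to 9.27). Among the 1719 probes with no gene name, which no comparison used, 38 were above background on each of the 9 progenitor arrays and on no embryonic stem cell array, and 28 the other way round.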

How the results depend on the processing

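The alternatives that were chosen only after the data had been seen were the scalings of the deposited values, the subtraction of the background level, the level at 3 SD and leaving out both day 0 replicate 3 and day 1 replicate 2.

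Among results that passed with or without the alternative, no named gene turned direction, and the 1 list that did was the acinar list between day 1 and day 0, at -0.24 without both day 0 replicate 3 and day 1 replicate 2, where its construction leaves out the arrays that stand lowest and highest for that list in their groups. Quantile normalization, cyclic loess and median scaling kept the side of the threshold of 377, 368 and 372 results for named genes (2, 10 and 7 lost it) and of 138, 135 and 135 results for lists, each counted once per comparison. The deposited values were already normalized between arrays, with near-equal quartiles, so quantile normalization in particular could change little. These scalings cannot show how far the results depend on the authors' own normalization. No filter kept 344 and 136 such results, and background subtraction kept 364 and 132. With a 2-fold threshold added, which can only lower a count, the comparisons called 131, 349, 73, 695, 1249 and 2382 genes (day 1 against day 0, day 4 against day 0, day 4 against day 1, adult islets against day 4 and day 0, and day 0 against embryonic stem cells) and the overlap was 217. With array weights the first 4 called 1036, 2970, 2892 and 3981 genes. With only the 2 groups compared, day 1 against day 0 called 168 genes, day 4 against day 1 14 and adult islets against day 4 4066. The groups differed in spread, which the main fit takes as equal. Arrays correlated at 0.995 within day 4 and 0.991 within adult islets, but as low as 0.960 within day 0 and 0.950 within day 1. Both day 4 arrays had a weight of 3.55, and the day 0 arrays had weights of 0.478 to 0.994. Unequal spread goes with these counts, though its share in them was not tested. Without both arrays named above, day 1 against day 0 called 260 genes from fewer samples. The overlap had a median of 492.5 genes with day 0 split, from fewer samples.

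Lists called (10, 9, 3, 10, 10 and 12 in the same order) became 0, 0, 0, 1, 1 and 5 with camera and an estimated correlation, with 5, 7 and 2 lists at an unadjusted p under 0.05 in the first 3, and fry called 18 for adult islets against day 0, the causes were not tested. Over all comparisons fry kept the side of the threshold of 115 results for lists, lost the call of 7 and gained that of 16. Leaving out 1 array at a time, the counts of genes ranged from 202 to 471, 193 to 1091, 8 to 359, 675 to 859, 1922 to 3434 and 4256 to 4979, those of lists from 8 to 10, 8 to 11, 2 to 7, 10 to 11, 9 to 11 and 11 to 12, and the overlap from 173 to 803. Over these settings 1797 results for named genes kept their side of the threshold, 348 lost the call and 4 gained it. Of the results for lists, 756 kept it, 11 lost it and 15 gained it. The percentage of called genes that were higher ranged over all alternatives from 38.7 to 57.2, 41.4 to 52.9, 43.1 to 91.7, 42.2 to 63.7, 40.7 to 54.8 and 47.8 to 56.5, so a majority of rises or of falls held throughout in 0 of the 6 comparisons.

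With the replicate number as a block, day 1 against day 0, day 4 against day 0 and day 4 against day 1 called 235, 570 and 23 genes and the overlap was 446. On the progenitor arrays alone the block gave 125, 328 and 0 genes (limma, 1301 at an unadjusted p under 0.05 in the last). Of the results for named genes, 307 kept their side of the threshold with the block on all arrays (69 lost the call), 76 on the progenitor arrays alone (69 lost it) and 321 with only the 2 groups compared (53 lost it). Deviations of same-numbered day 0 and day 1 arrays correlated at 0.29, -0.09 and -0.31, and 1 of 3 day 1 arrays correlated best with its own number. With so few pairs, and deviations taken from means of the same arrays, this check could hardly show a pairing. The other groups were not checked, so whether the numbers mark a pairing stays open.

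Alternatives not run were a fit without background correction and scalings of background-corrected signals, because signals before normalization could not be matched to samples, filters on detection p-values for the same reason, and a slide block, because no slides are given. The deposited values, planned as an alternative, became the source of all results. Signal over background limits what dim probes can show: more than 50% of the probes on each array lay under the background level.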

Other observations

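The tests of endoplasmic reticulum chaperones and of imprinted genes were chosen only after related results were seen, as was that of Atf4 targets, whose list was written before the values of its members were seen.

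Several gene groups that accompany endocrine differentiation did not pass as sets with camera along the time course. Genes repressed in beta cells had a median of -0.10 at day 1 (adjusted p = 0.378), -0.33 at day 4 against day 0 (adjusted p = 0.0764) and -0.51 in adult islets against day 0 (adjusted p = 0.0527), where 5 of 15 fell and 0 rose (0 higher and 5 lower adjusted over the list alone). Notch and Id genes had 2 of 17 lower at day 4 than at day 0 and 0 higher (1 higher and 2 lower adjusted over the list alone, median -0.22, adjusted p = 0.243), Mfng among them (-2.24 ± 0.24). Among sirtuin, deacetylase and NAD genes, 6 of 21 fell and 2 rose in adult islets against day 0 (2 higher and 6 lower adjusted over the list alone, median -0.07, adjusted p = 0.291), with the deacetylases Hdac1 at -1.07 ± 0.14 and Hdac2 at -1.04 ± 0.15. The maintenance methylation factor Uhrf1 fell from day 4 to adult islets (-2.62 ± 0.48), while its Polycomb and DNA methylation list did not pass (median -0.35, 0 higher and 2 lower adjusted over the list alone, adjusted p = 0.0736). With fry, which does not compare a list with other genes, 3 of these results passed, those of the genes repressed in beta cells and of the sirtuin list in adult islets against day 0 and of the Polycomb list against day 4.

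Chac1, Slc7a3, Aldh1l2 and Asns rose at day 1. A wider rise of genes known as targets of the transcription factor Atf4 was tested on 31 other targets. Their median difference was 0.43, with 11 higher and 0 lower (camera adjusted p = 4.92e-12 over 24 tests). With an estimated correlation the adjusted p was 0.04996, just under the threshold. Whether Atf4 activity itself rose on the first day was not tested. Atf5 had been seen to vary before the test and was taken out of the list after a first run, and with it the median was 0.56 (adjusted p = 0.0347 with an estimated correlation). A rise of the chaperones of the endoplasmic reticulum along with them is argued against by a median of -0.079 over 12 chaperones, with 0 higher and 0 lower (adjusted p = 0.417). At day 4 the Atf4 targets had a median of 0.26 against day 0, 9 higher and 1 lower (adjusted p = 5.44e-05, and adjusted p = 0.127 with an estimated correlation).

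Dlk1 and Nnat, both imprinted, were among the largest falls from day 4 progenitors to adult islets. A wider fall of imprinted genes stays open: 30 others had a median of -0.21, with 7 lower and 1 higher (adjusted p = 0.0671, and adjusted p = 0.127 with an estimated correlation). The growth factor Igf2 (-3.89 ± 0.70), the cell cycle inhibitor Cdkn1c (-3.53 ± 0.83) and the receptor adaptor Grb10 (-2.19 ± 0.16), which were picked after their values were seen, fell.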
